A study of Mus musculus with 8 samples.

How the data were processed

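Strand-specific, poly(A)-selected libraries of EpCAM-positive mouse esophageal epithelial cells were made with the NEBNext Ultra II kit and sequenced as 150-base read pairs on a NovaSeq, per the labels' protocols, from RNA with an integrity number of at least 8. The deposited values are estimated counts per transcript and TPM per transcript for 8 libraries. Per the file headers the columns are 1 per library, and kallisto is named only as the quantifier in the tables' titles; its version and index are not given in the sources used here. The submitters' processing notes name FastQC, MultiQC, cutadapt, STAR, R 4.3 and DESeq2 and the build GRCm39 (mm39), without a role for any of them. The estimated counts were whole numbers as deposited by the authors, and the deposited TPM were normalized within each library. TPM values served only as alternatives and for choosing the most abundant protein-coding transcript of a gene, from which its structure was taken.

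Transcript identifiers were joined to GENCODE M21 (GRCm38) by identifier and version. Of 118489 identifiers 116728 matched, and the 1761 that did not, which held between 0.483% and 0.549% of the counts of a library, were left out. Coordinates are those of GRCm38, since the identifiers carry its versions, and were not moved to the build in the processing notes. Estimated counts were summed per gene, which gave 35968 genes. The non-coding RNA Xist was not analysed here, so the sex of each library was read from Ddx3y, with Kdm5d and Eif2s3y dividing them alike, which showed 2 male and 2 female wild-type libraries and 4 female knockout libraries. Sex as a covariate was planned only for the case of both sexes in both groups. Group and sex terms can still be fitted, with the sex term resting on the wild type, and that fit was added after seeing the data.

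Groups follow the labels, with 4 wild-type and 4 Mettl3 knockout libraries, numbered in the order of deposit. Library totals lay between 13284284 and 25042301 estimated counts. No pair of libraries of a group agreed within sampling noise (chi-square per gene from 25.5 to 143.0). Genes were kept with edgeR 4.0.16 filterByExpr, scaled by TMM and tested with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library totals. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic, and the 95% interval of the Sox2 ratio used 6 residual degrees of freedom. The biological coefficient of variation was 0.214. A gene with 0 counts in a group was given a bound from a floor of 3 counts over the group. Counting intervals at 95% are exact binomial and cover counting error only.

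Gene lists were fixed before the data were examined. They covered m6A machinery, basal, suprabasal, skin and columnar epithelium, lineage transcription factors, G1/S, G2/M, p53, interferon, inflammation, the integrated stress and unfolded protein responses, immediate-early genes, SOCS, Notch, Wnt, EGFR, YAP, TGF-beta, apoptosis, ribosomal proteins, oxidative phosphorylation, cholesterol, glycolysis, NRF2 and mitochondrial transcripts. Others held markers of immune, fibroblast, endothelial, muscle, neural, thyroid, airway and red blood cells. The 26 lists with 5 or more tested members were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Loricrin and RIG-I, in the skin and interferon lists, were matched by their older symbols Lor and Ddx58. Transcripts were tested as genes were, and transcript use with limma voom and diffSplice.

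Genes named in the text were Mettl3 and Sox2, the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean log2 CPM of at least 3 and groups that do not overlap (without predicted genes and pseudogenes), and up to 3 members of each list past the threshold by smallest p. A list with no member past it gave up to 2. Every member of the m6A list could be named. For transcript use, Mettl3 and 4 genes with the smallest p and a share moved by 10 points were named. Genes outside this rule, such as the few members of a list that went against the rest, were chosen after their values were seen.

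Each step was tested on simulated counts drawn from the real means, dispersions and library sizes. At gene level 79.2% of simulated changes of log2 size 1 and 88.9% of size 2 were recovered, with 2.89% of calls false, over 12380 genes. That simulation changed 101 genes by size 1 and 99 by size 2, far fewer than the 6851 called in the real data. Its rates may thus differ from those of the real comparison. At transcript level 6.93% and 35.6% were recovered, with 2.50% false, over 30844 transcripts. The shifted list was called and 0 of the other lists. Genes were drawn independently of each other there, so false calls from genes that move together could not appear. For transcript use 29.7% of simulated changes were recovered and 13.4% of calls were false, over 7676 genes, so calls of transcript use hold more false ones than the threshold implies.

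The alternatives were DESeq2 1.42.0 size factors and Wald test, library totals alone, limma voom, no filter and a stricter filter (CPM of 1 in 4 libraries), an offset for transcript length, TPM with pseudocounts of 1 and 0.1, a 2-fold threshold, counts thinned to the smallest library, 1 surrogate variable (sva 3.50.0), protein-coding genes alone, edgeR diffSpliceDGE for transcript use, and each library left out in turn. Sex as a covariate, female libraries alone, a comparison without genes on chromosomes X and Y, and TMM factors without the most abundant 1 percent of genes were added after seeing the data. R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.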

Results

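Bulk RNA sequencing was done on epithelial cells sorted from the mouse esophagus by the surface protein EpCAM. Dead cells and immune cells were excluded in the sort. There were 4 wild-type samples and 4 samples taken 6 days after deletion of Mettl3 by an inducible Cre recombinase (CreER) driven by Sox2. Mettl3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. The labels describe 4 biological replicates per group. Each library held between 13284284 and 25042301 estimated counts over 118489 transcripts, and the 8 libraries were compared at the level of genes, gene lists, transcripts and transcript use. The question, as stated by the submitters, was which transcripts change early after Mettl3 is lost. Libraries are named by group and number, and the numbers pair no samples.

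The targeted gene was examined first. Mettl3 (ENSMUSG00000022160.18, chromosome 14, 52294841 to 52305128, minus strand, GRCm38) measured 40.4 ± 2.19 CPM (SD, n = 4) in wild type and 8.96 ± 1.15 CPM (SD, n = 4) in the knockout. Its log2 fold change was -2.17 (SE 0.11), with an adjusted p of 1.69e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 4 knockout libraries lay below all 4 wild-type libraries. The mix of Mettl3 transcripts changed too. The canonical coding transcript ENSMUST00000022767.15 made up 86.3% ± 5.48 (SD, n = 4) of Mettl3 counts in wild type and 22.6% ± 2.12 (SD, n = 4) in the knockout. Transcript ENSMUST00000147768.7, annotated as a target of nonsense-mediated decay, made up 6.42% ± 2.10 (SD, n = 4) and 52.3% ± 12.4 (SD, n = 4). That transcript lacks exon 4 of the canonical one, a coding exon of 176 nucleotides at 52298640 to 52298815 on chromosome 14, and ends in a longer last exon. None of the other 4 tested Mettl3 transcripts overlaps exon 4. Shares rest on the division of reads among overlapping transcripts, whose uncertainty was not used here.

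Sox2 (ENSMUSG00000074637.7, chromosome 3, 34650405 to 34652461, plus strand), a transcription factor of esophageal progenitors and the driver of the Cre, fell from 179.9 ± 12.5 CPM (SD, n = 4) to 88.8 ± 9.94 CPM (SD, n = 4). The log2 fold change was -1.02 (SE 0.10, edgeR adjusted p = 7.91e-05), and the fitted ratio of knockout to wild type was 0.494 with a 95% interval of 0.419 to 0.582. The labels do not give the Cre status of the wild-type mice.

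**Figure D1:**
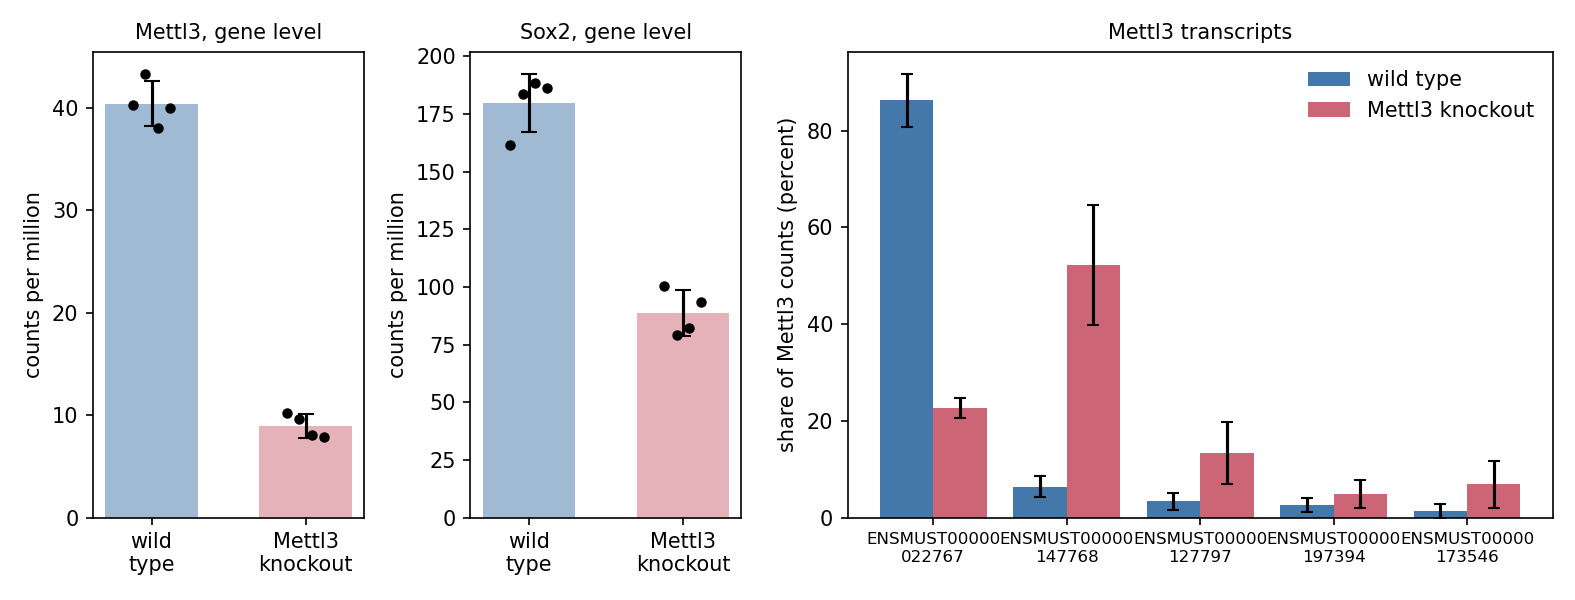
Level (CPM) of Mettl3 and Sox2 in each library (points) with group means (bars) and SD (error bars, n = 4), and the share of Mettl3 counts in each of 5 tested Mettl3 transcripts (mean and SD, n = 4). Mettl3 averages 40.4 CPM in wild type and 8.96 CPM in the knockout, and the canonical transcript goes from 86.3% to 22.6% of its counts.

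The knockout differed from wild type across much of the transcriptome, with rises and falls in near-equal number. Cornified-envelope genes of the Sprr2 cluster, the wound-associated keratin Krt16 and interferon-induced genes showed the largest rises. Dcn, a matrix proteoglycan, the crosslinking enzyme Tgm2 and Ccn2, a matricellular YAP target, were among the largest falls. Of 12531 genes tested, 6851 changed (edgeR, Benjamini-Hochberg adjusted p under 0.05), 3461 higher and 3390 lower, which is 54.7% of the genes tested. A change of at least 2-fold was seen in 1236 higher and 1096 lower genes, and of at least 4-fold in 430 and 264. In 6351 genes (50.7%) the libraries of the groups did not overlap, against 2.86% by chance. The first principal component held 70.0% of the variance and separated the groups. Y-linked genes put 2 of the 4 wild-type libraries and 0 of the 4 knockout libraries as male. Among the female libraries alone, 5010 genes changed, 2577 higher and 2433 lower, of which 2440 and 2399 were also called in the comparison of all 8. With sex as a covariate 5211 changed, 2652 higher and 2559 lower.

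Krt16 (chromosome 11, 100246091 to 100248902) went from 11.2 ± 4.84 to 3658 ± 2785 CPM (SD, n = 4 each; log2 fold change 8.35, SE 0.91, edgeR adjusted p = 0.000131). Sprr2d rose by a log2 fold change of 10.30 (SE 1.18, edgeR adjusted p = 0.000159) and Sprr2f by 10.35 (SE 1.11). Sprr2e had 0 counts in wild type, and its pooled knockout level was 681-fold above a floor of 3 counts over the wild-type group. Its lower 95% counting limit was 553-fold. It measured 1.59 CPM in knockout library 1 and 23.9 to 58.0 CPM in the other knockout libraries. Ifit1, an interferon-induced RNA-binding protein, rose by 8.77 (SE 1.62, edgeR adjusted p = 0.00168). Slfn2, Slfn4 and Ifi204 had 2, 1 and 2 wild-type counts, and their ratios of knockout to wild type were 2224 (95% counting interval 615 to 18367), 2323 (417 to 91785) and 491 (135 to 4056). Knockout library 2 carried much of these, and without it the ratios were 743 (205 to 6143), 322 (57.4 to 12781) and 109.8 (29.98 to 913). Without wild-type library 4, Slfn2 and Slfn4 had 0 wild-type counts and were 1114-fold and 582-fold above that floor (lower 95% counting limits 906 and 473). The log2 fold change of Ifit1 was 6.66 without knockout library 2 and 10.497 without wild-type library 4, and those of Sprr2d and Sprr2f were 11.64 and 11.54 without wild-type library 1. Reads of the Sprr2, Slfn and Ifi families can be shared among near-identical copies, so the level of a single member is uncertain. By limma voom, Sprr2e, Sprr2f, Sprr2d, Slfn2, Slfn4, Ifi204 and Ifit1 kept their direction and did not pass the threshold (adjusted p from 0.0596 to 0.133).

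Dcn fell from 45.9 ± 23.6 to 0.265 ± 0.211 CPM (SD, n = 4 each; log2 fold change -7.28, SE 0.59, edgeR adjusted p = 4.78e-05). Tgm2 changed by -6.99 (SE 0.91) and Ccn2 by -6.15 (SE 0.82). Il1r2, the decoy receptor for interleukin-1, fell from 229.8 ± 28.7 to 4.63 ± 4.90 CPM (SD, n = 4 each; edgeR adjusted p = 0.000159). The sulfotransferase Sult1d1, the cytochrome Cyp4b1, Egfl6 and the aminopeptidase Xpnpep2 changed by -6.60, -4.86, -4.80 and -4.54 on the log2 scale (SE 0.94, 0.44, 0.59 and 0.49). Tgm2 did not pass by limma voom (adjusted p = 0.0572). Without knockout library 1 the changes were larger, at -8.08 for Dcn, -7.32 for Ccn2, -6.58 for Il1r2, -8.68 for Sult1d1, -5.73 for Cyp4b1, -6.10 for Egfl6 and -5.40 for Xpnpep2. Sult1d1 changed by -5.70 without wild-type library 4, and Tgm2 by -7.75 without knockout library 4.

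Other members of the m6A machinery, the writers, readers and erasers of the mark, were mostly higher. Of 19 tested, 11 rose, 3 fell (Mettl3, Fto and Hnrnpc) and 5 did not pass, with the same counts adjusted over the list alone. The readers Ythdf2, Ythdf1 and Ythdf3 rose by log2 fold changes of 1.37 (SE 0.10), 0.90 (SE 0.09) and 0.56 (SE 0.09). The writer-complex members Rbm15, Virma, Cbll1, Wtap and Zc3h13 rose by 1.48, 0.62, 0.61, 0.45 and 0.37 (SE 0.11, 0.08, 0.13, 0.07 and 0.10), as did the separate methyltransferase Mettl16 by 0.90 (SE 0.10). Alkbh5 and Hnrnpa2b1 rose by 0.26 and 0.33 (SE 0.09 and 0.11), and Fto and Hnrnpc fell by 0.35 and 0.29 on the log2 scale (SE 0.08 and 0.11). The edgeR adjusted p of Hnrnpa2b1, Alkbh5 and Hnrnpc lay between 0.0297 and 0.0394, and each was lost without any of several libraries: Hnrnpa2b1 without wild-type library 1, 2 or 4 or knockout library 2, 3 or 4, Alkbh5 without wild-type library 1, 3 or 4 or knockout library 2, 3 or 4, and Hnrnpc without wild-type library 3 or 4 or knockout library 1, 2 or 4. With sex as a covariate Fto, Zc3h13, Hnrnpa2b1, Hnrnpc and Alkbh5 did not pass (edgeR adjusted p = 0.0609, 0.0765, 0.119, 0.195 and 0.225). Mettl14, the partner of Mettl3, measured 27.3 ± 1.32 and 23.9 ± 3.01 CPM (SD, n = 4 each; edgeR adjusted p = 0.165). Ythdc1, Ythdc2, Rbm15b and Igf2bp2 had log2 fold changes of 0.14, 0.16, -0.02 and -0.94 and did not pass, though Igf2bp2 did by limma voom (adjusted p = 0.0437) and without knockout library 3 (edgeR adjusted p = 0.0152). As a set the list was higher (limma camera adjusted p = 0.0403; adjusted p = 0.687 with an estimated correlation), and the call was lost without wild-type library 1 (adjusted p = 0.0552) or knockout library 3 (adjusted p = 0.0571), with 1 surrogate variable (0.0523), on log2 TPM (0.0607) and among female libraries (0.0518).

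Genes of basal keratinocytes, the progenitor layer, were lower, and genes of the differentiating layers above it were higher. Of 19 basal genes, 12 fell, 1 rose and 6 did not pass, with the same counts adjusted over the list alone. Trp63, the master transcription factor of stratified epithelia, fell from 864 ± 114 to 385 ± 17.5 CPM (SD, n = 4 each; log2 fold change -1.17, SE 0.11, edgeR adjusted p = 7.76e-05). Lama3, a chain of the basement-membrane laminin, and Dst, a hemidesmosome plakin, changed by -1.70 (SE 0.14) and -2.25 (SE 0.26). Krt14, a basal keratin named here after its values were seen, was the 1 that rose, by 1.63 (SE 0.30, edgeR adjusted p = 0.00171). Of 33 suprabasal genes, 22 rose, 1 fell (Emp1, -1.30, SE 0.21) and 10 did not pass; adjusted over the list alone, 23 rose and 1 fell. Spink5, a protease inhibitor of the barrier, rose by 3.40 (SE 0.28, edgeR adjusted p = 4.95e-05), and Sprr2h by 8.12 (SE 0.88). The abundant suprabasal keratins Krt4 and Krt13, also named after their values were seen, had log2 fold changes of 0.43 (SE 0.27) and 0.30 (SE 0.18) and did not pass. The limma camera adjusted p was 0.00145 for the basal list (adjusted p = 0.555 with an estimated correlation) and 7.30e-05 for the suprabasal list (adjusted p = 0.687 with an estimated correlation).

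Of the genes of skin-type cornification, 7 of 20 had counts enough to be tested. Of these 5 rose and 2 did not pass, also adjusted over the list alone. Krt10, a keratin of the skin, rose by 3.70 (SE 0.48, edgeR adjusted p = 0.000287), and the late-envelope genes Lce3a and Lce3c by 5.41 (SE 1.25) and 4.60 (SE 1.11). The list did not pass (limma camera adjusted p = 0.0695; adjusted p = 0.609 with an estimated correlation), but it did without wild-type library 1 or 2 or knockout library 2 or 3 (adjusted p from 0.00582 to 0.0476), with no filter (0.00357) and by limma fry (0.0181). Without knockout library 4, Lce3a and Lce3c rose by 4.21 and 3.73, without wild-type library 1 by 9.02 and 7.19, and without knockout library 3 Krt10 rose by 3.11. Among 13 esophageal lineage transcription factors, 6 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone. Zfp750, a differentiation factor, rose by 0.96 (SE 0.12), while Sox2 and Trp63 were among those that fell. The camera adjusted p was 0.947. Only 4 of 22 columnar epithelium genes were expressed highly enough to test, and 1, Lgals4, fell (-2.39, SE 0.58; -2.99 without knockout library 1).

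Most genes of the G1/S transition of the cell cycle were higher. Of 27 G1/S genes, 25 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone. Ccne1 (cyclin E1), the flap endonuclease Fen1 and the ribonucleotide reductase subunit Rrm2 rose by log2 fold changes of 3.22 (SE 0.27), 2.66 (SE 0.20) and 1.70 (SE 0.19), with edgeR adjusted p values of 5.81e-05, 4.40e-05 and 0.000152. Of 26 G2/M genes, 11 rose, 1 fell (Nusap1) and 14 did not pass, also adjusted over the list alone. Birc5, Aurka and Cdk1 rose by 1.25 (SE 0.20), 1.20 (SE 0.21) and 0.90 (SE 0.16). The limma camera adjusted p was 3.73e-10 for G1/S (adjusted p = 0.584 with an estimated correlation) and 0.00145 for G2/M (adjusted p = 0.849 with an estimated correlation), and by limma fry the G2/M list did not pass (adjusted p = 0.0942).

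Targets of the tumor suppressor p53 rose in 21 of 26 cases, with 3 falls (Sesn1, Btg2 and Trp73) and 2 not past, also adjusted over the list alone. Eda2r, the nuclease Aen and Mdm2, the ubiquitin ligase that restrains p53, rose by 2.61 (SE 0.18), 1.44 (SE 0.10) and 1.23 (SE 0.09), with edgeR adjusted p values of 3.60e-05, 3.70e-05 and 4.00e-05. Of 15 genes of the unfolded protein response, 13 rose and 0 fell, also adjusted over the list alone, among them Pdia4, Creld2 and Manf (0.91, 1.04 and 0.997; SE 0.09, 0.11 and 0.11). Of 21 genes of the integrated stress response, 13 rose, 1 fell (Vldlr) and 7 did not pass; adjusted over the list alone, 14 rose and 2 fell. Cebpb, the cystine transporter Slc7a11 and Chac1 rose by 1.10 (SE 0.08), 3.87 (SE 0.35) and 3.56 (SE 0.41), while Atf3 and Ddit3, named after their values were seen, had log2 fold changes of -1.37 (SE 0.60) and -0.53 (SE 0.20) and did not pass. The limma camera adjusted p was 1.78e-07 for p53 targets, 2.31e-05 for the unfolded protein response and 0.00531 for the integrated stress response (adjusted p = 0.555 with an estimated correlation in each).

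Interferon-stimulated genes and inflammatory genes were higher in the knockout, but unevenly among its libraries. Of 34 interferon-stimulated genes, 26 rose, 1 fell (Ifi27) and 7 did not pass; adjusted over the list alone, 27 rose and 1 fell. Oasl1, Isg15 and Rtp4, all induced by interferon, rose by 7.58 (SE 1.06), 6.57 (SE 1.16) and 6.03 (SE 0.9999), and without knockout library 2 by 6.37, 5.003 and 4.92. The summed level of the list was 781, 4136, 386 and 1495 CPM in knockout libraries 1 to 4, against 434, 444, 445 and 549.7 CPM in wild-type libraries 1 to 4. The sum in knockout library 3 was thus below every wild-type sum, and the median member in it lay 0.08 above the wild-type mean on the log2 scale. Single members were nonetheless higher there than in any wild-type library, as for Oasl1 (17.7 CPM against at most 0.365), Isg15 (12.8 against 2.07), Rtp4 (8.36 against 1.44) and Ifit1 (5.86 against 0.460). The median log2 fold change of the list was 3.30, also with the 1 member at 0 counts in a group set to its bound. By limma voom 7 of the list rose, without Oasl1, Isg15 and Rtp4 (adjusted p from 0.0598 to 0.0890), and among female libraries 13 rose. The limma camera adjusted p was 0.0111 (adjusted p = 0.849 with an estimated correlation), and limma fry, which asks whether the genes move one way, gave an adjusted p of 0.268.

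Of 15 inflammatory cytokines and NF-kB targets, 11 rose, 0 fell and 4 did not pass, also adjusted over the list alone. Il1f6 (interleukin-36 alpha), Il1f9 (interleukin-36 gamma) and Nfkb2 rose by 7.14 (SE 0.90), 2.40 (SE 0.31) and 1.04 (SE 0.10; limma camera adjusted p of the list = 0.00547; adjusted p = 0.568 with an estimated correlation). The summed level of this list was 755, 2302, 1625 and 1170 CPM in knockout libraries 1 to 4, and 365 to 523 CPM in wild type. Immune cell markers, most of whose sum was H2-Ab1, summed to 23.7 ± 2.34 CPM in wild type and 21.8 ± 1.68 in the knockout (SD, n = 4 each), with 3 of 24 expressed highly enough to test. Another list, of 25 leukocyte markers and chosen after the data were seen, went from 17.9 ± 1.35 to 49.1 ± 6.04 CPM (SD, n = 4 each). Of the 3 tested, Cd68, a lysosomal protein of macrophages, rose from 2.41 ± 0.552 to 6.58 ± 1.25 CPM, and H2-Ab1 and Cd3d fell (-0.65, SE 0.16, and -1.45, SE 0.47).

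**Figure D2:**
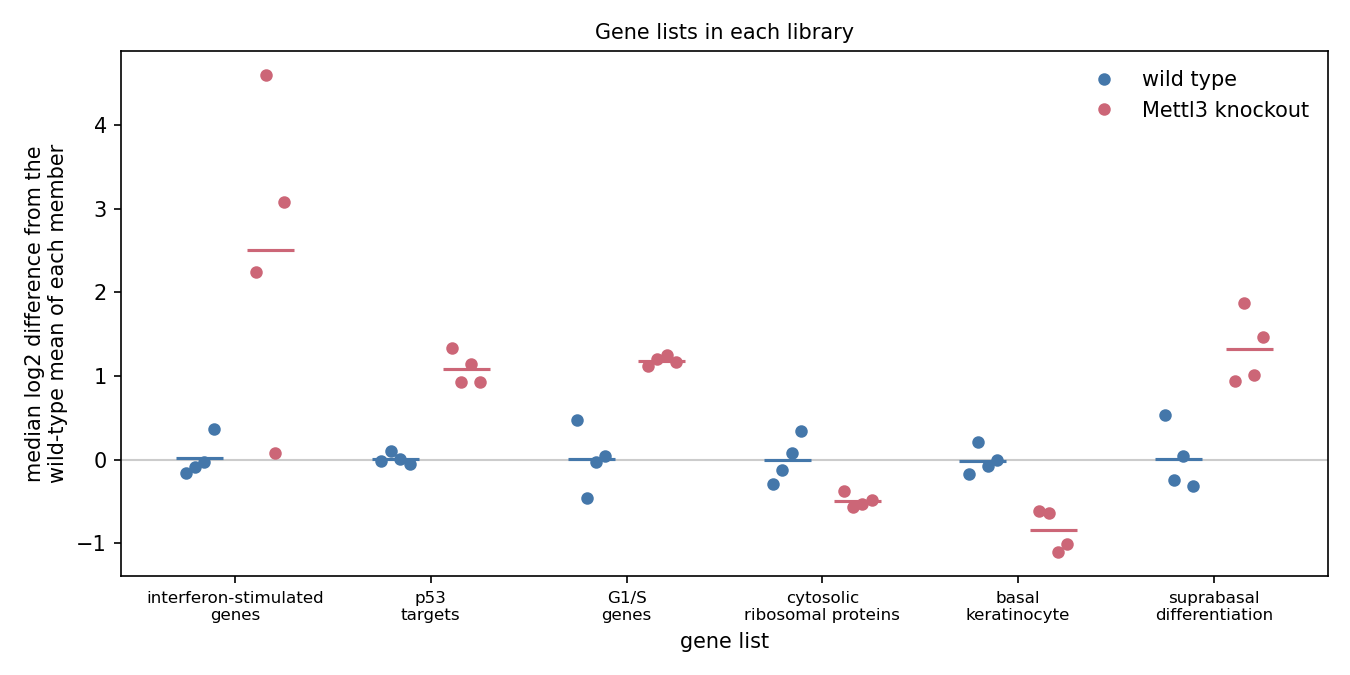
Median over list members of the log2 difference from the wild-type mean of each member, for 6 gene lists (x axis) in each wild-type and knockout library (points; lines are group means). The interferon-stimulated list spreads from 0.08 in knockout library 3 to 4.59 in knockout library 2, while the p53 target list stays between 0.93 and 1.34 in the 4 knockout libraries.

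Cytosolic ribosomal protein genes were lower. Of 79, 58 fell, 0 rose and 21 did not pass; adjusted over the list alone, 62 fell. Rpl17, Rpl28 and Rpl10 changed by log2 fold changes of -0.91 (SE 0.17), -0.69 (SE 0.12) and -0.63 (SE 0.10), with edgeR adjusted p values of 0.00199, 0.00106 and 0.000929. The list summed to 70664 ± 12887 CPM in wild type and 49878 ± 2859 CPM in the knockout (SD, n = 4 each; limma camera adjusted p = 2.81e-09; adjusted p = 0.843 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes with which reads can be shared. Of 77 oxidative phosphorylation genes, 18 rose, 12 fell and 47 did not pass (16 and 12 adjusted over the list alone), with Ndufa4, Uqcrfs1 and Uqcr10 among the rises (2.28, 0.91 and 0.62; SE 0.22, 0.10 and 0.08). Of 13 mitochondrially encoded transcripts 1, mt-Nd6, rose (0.85, SE 0.26; lost without wild-type library 2 or knockout library 1, and with sex as a covariate), and 0 adjusted over the list alone.

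A further 6 lists, all of signalling genes with members in both directions, did not pass by limma camera, though the EGFR list passed by limma fry as higher (adjusted p = 0.0362). Among 22 EGFR ligands and MAPK feedback genes, 10 rose and 4 fell (10 and 6 adjusted over the list alone), with Etv4 and Phlda1 up (3.41, SE 0.18; 2.09, SE 0.22) and Spred2 down (-1.82, SE 0.20). Among 14 Notch genes, 2 rose and 5 fell, including the coactivators Maml2 and Maml3 (-2.04, SE 0.20; -0.58, SE 0.12) and the glycosyltransferase Lfng (-1.92, SE 0.25). Among 16 Wnt genes, 3 rose and 7 fell, with the receptors Lgr4 and Fzd10 down (-1.46, SE 0.16; -1.43, SE 0.18) and Tcf7 up (1.59, SE 0.24). Of 14 YAP targets, 3 rose and 7 fell, among them Nuak2 (0.76, SE 0.08) and Amotl1 (-0.70, SE 0.09). Of 20 TGF-beta and BMP genes, 5 rose and 6 fell, with Tgfb2 down (-2.37, SE 0.48) and Skil up (0.46, SE 0.10). Skil did not pass among female libraries alone (edgeR adjusted p = 0.0639). Of 8 SOCS genes, 3 rose and 2 fell, with Socs1 and Socs5 up (1.77, SE 0.27; 1.09, SE 0.15) and Socs7 down (-0.68, SE 0.10). Counts for the Notch, Wnt, YAP, TGF-beta and SOCS lists were equal when adjusted over the list alone. The limma camera adjusted p of these 6 lists lay between 0.211 and 0.614.

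Of 24 apoptosis regulators, 11 rose and 6 fell (11 and 7 adjusted over the list alone), with Ripk3 and Birc3 up (1.59, SE 0.18; 1.47, SE 0.23) and Casp9 down (-0.83, SE 0.11), and the list passed by limma fry as higher (adjusted p = 0.0362). Of 19 targets of the antioxidant factor NRF2, 7 rose and 5 fell (7 and 6 adjusted over the list alone), with Hmox1 and Txnrd1 up (1.94, SE 0.22; 0.88, SE 0.10). Of 20 glycolysis and hypoxia genes, 9 rose and 3 fell (9 and 5 adjusted over the list alone), including Hk2 and Vegfa (0.68, SE 0.11; 1.06, SE 0.21) and Egln3 (-0.76, SE 0.13). Of 20 cholesterol synthesis genes, 2 rose and 1 fell, with Sqle among the rises (0.60, SE 0.23) and Hmgcs1 the fall (-0.51, SE 0.18), and 0 adjusted over the list alone. The call of Sqle was lost with sex as a covariate and without wild-type library 2 or 4 or knockout library 1, 3 or 4, and that of Hmgcs1 without wild-type library 2, 3 or 4 or knockout library 3. Of 21 immediate-early and dissociation stress genes, 6 rose and 7 fell, also adjusted over the list alone, with the heat-shock genes Hspa1a and Hspa1b and Ier5 up (2.26, SE 0.27; 1.91, SE 0.19; 1.26, SE 0.12). The limma camera adjusted p of these lists and of the oxidative phosphorylation and mitochondrial lists lay between 0.180 and 0.614. The cholesterol list passed without wild-type library 1 or knockout library 2 (adjusted p = 0.0305 and 0.0301) and with no filter (0.0436), and the oxidative phosphorylation list without wild-type library 3 (adjusted p = 0.0359). With all 8 libraries and an estimated correlation their adjusted p was 0.849 and 0.862. For the glycolysis list the median log2 fold change was -0.01 while the mean was 0.08.

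Few markers of other cell types were expressed highly enough to test, and those that changed went mostly down. Of fibroblast markers 4 of 16 were tested, with Dcn and Sparc down (Sparc -1.49, SE 0.17) and Fbln1 up (0.85, SE 0.15), and the list summed to 122.5 ± 20.6 CPM in wild type and 86.5 ± 10.7 CPM in the knockout (SD, n = 4 each). Dcn alone fell by more than that sum did, from 45.9 to 0.265 CPM, so the other fibroblast markers together did not fall. Of endothelial markers 4 of 14 were tested, with Flt1 down (-1.70, SE 0.37) and Egfl7 up (1.57, SE 0.44), both at under 3 CPM. Of muscle markers 3 of 18 were tested, with Acta2 and Tnni2 down (-1.19, SE 0.35; -0.78, SE 0.24). Of neural and glial markers 3 of 12 were tested, with Tubb3 up (4.56, SE 0.46) and Mbp down (-0.43, SE 0.08). Of thyroid markers 2 of 10 were tested, and Foxe1, also a factor of the foregut epithelium, rose (0.94, SE 0.22). Of airway markers 2 of 12 were tested, and the cytochrome Cyp2f2 fell from 1812 ± 362 to 180.4 ± 154.7 CPM (SD, n = 4 each; log2 fold change -3.33, SE 0.58; -4.04 without knockout library 1). Cyp2f2 made up most of the summed airway level, which was 1999.7 ± 383.3 CPM in wild type and 326.5 ± 164.2 CPM in the knockout (SD, n = 4 each). Red blood cell markers had 0 of 7 tested, with summed levels of 1.10 and 0.743 CPM. These counts were equal when adjusted over each list alone. The call of Acta2 was lost without wild-type library 1, that of Tnni2 without wild-type library 2, and that of Cd3d without wild-type library 1 or 4 or knockout library 3 or 4. Acta2 and Cd3d also did not pass with sex as a covariate. Among female libraries alone Acta2, Tnni2, Cd3d and Foxe1 did not pass (edgeR adjusted p = 0.151, 0.0679, 0.159 and 0.0566). With an offset for transcript length the log2 fold changes of Flt1 and Egfl7 shrank to -0.33 and 0.96, and neither passed (edgeR adjusted p = 0.735 and 0.196).

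Together 11 of the 26 lists with 5 or more tested members passed by limma camera with a preset correlation of 0.01, 9 higher and 2 lower. With an estimated correlation 0 passed. When the 8 libraries were divided in other ways into 4 and 4, up to 16 lists passed. Of the 35 divisions, the real one included, 17 gave 11 or more, so the number of lists past the threshold carries little weight. Many of these divisions keep most libraries of a group together and so hold part of the group difference, so they are not free of it. Member counts are not independent evidence either, since members can move together (estimated correlation from -0.0148 for lineage factors to 0.884 for mitochondrial transcripts). Beside them stands the share over all genes tested, of which 54.7% changed, 50.5% of those higher. By limma fry 12 lists passed with a direction and 23 in either direction.

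**Figure D3:**
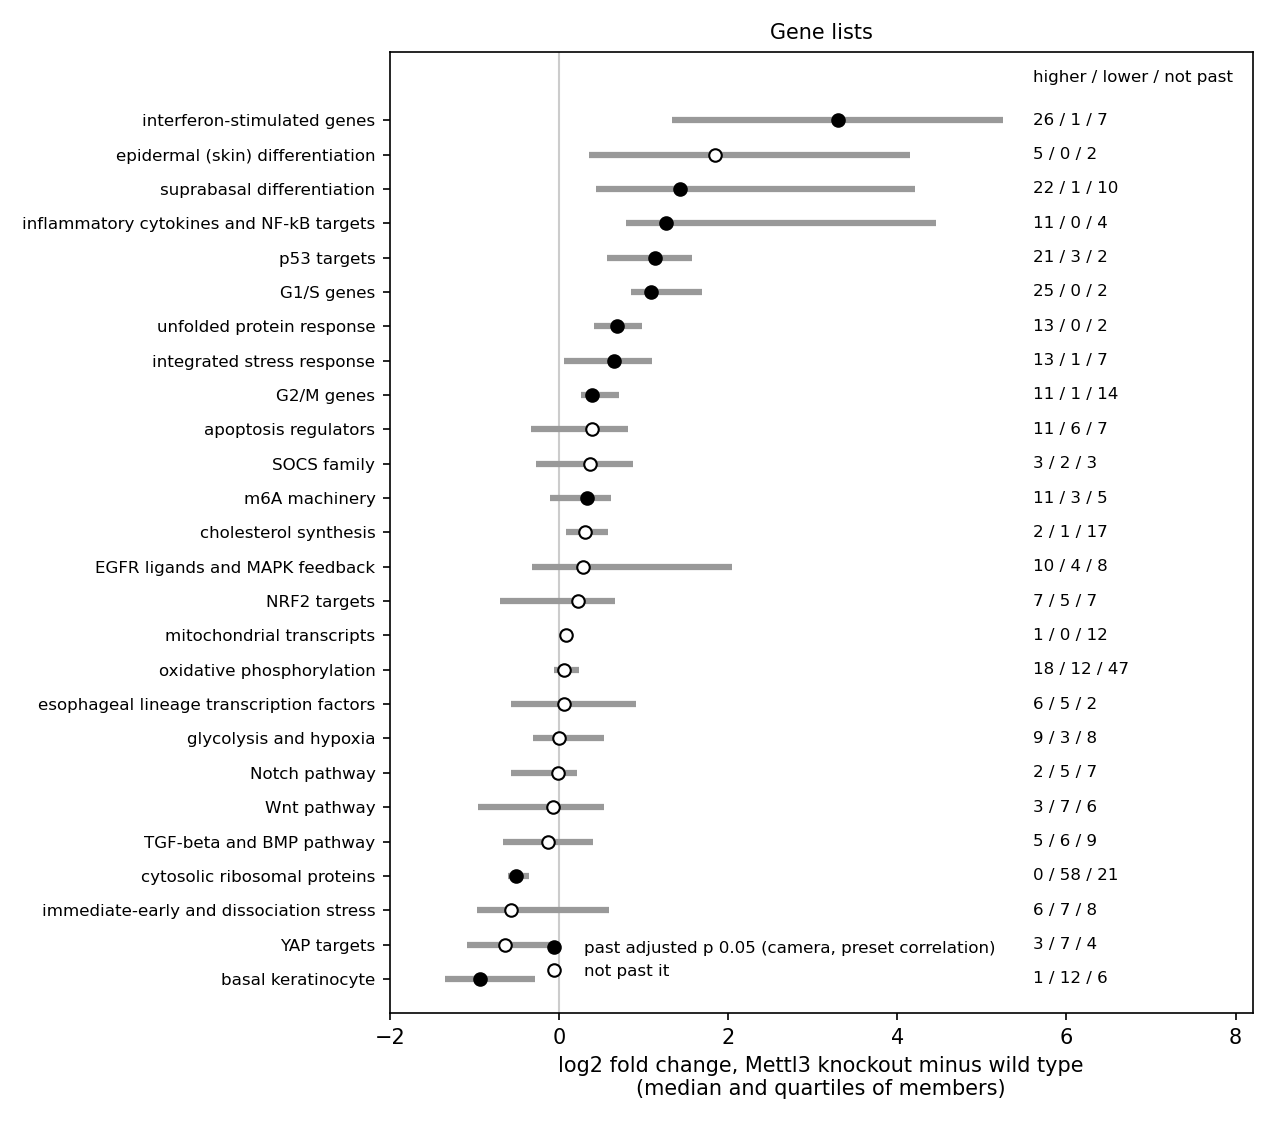
Median (points) and quartiles (bars) of the log2 fold change of tested members for the 26 gene lists, with the numbers of members higher, lower and not past the gene-level test. Filled points mark the 11 lists past an adjusted p of 0.05 by camera with a preset correlation, of which 0 pass with an estimated correlation; the median is 3.30 for interferon-stimulated genes and -0.94 for basal keratinocyte genes.

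At the level of transcripts, 5383 of 33864 changed, 2905 higher and 2478 lower (edgeR, Benjamini-Hochberg). Among female libraries alone the number was 1581, with sex as a covariate it was 2338, without knockout library 3 it was 3507, and without wild-type library 4 it was 3587. The mix of transcripts within a gene changed in 411 of 8212 genes (limma diffSplice, F test, Benjamini-Hochberg), with a share moved by 10 percentage points or more in 291. Among female libraries alone 94 genes passed. Without wild-type library 1, 2 or 4 the number was 229, 175 and 271, and without knockout library 2, 3 or 4 it was 216, 237 and 266. Besides Mettl3 (adjusted p = 4.36e-08), the named genes were Tor1aip2, Sar1a, Phb and Slc25a37, with limma diffSplice adjusted p values of 1.19e-11, 6.09e-08, 1.83e-07 and 5.48e-07. In Tor1aip2, transcript ENSMUST00000060404.4 went from 36.4% ± 3.60 to 59.9% ± 1.56 of counts and ENSMUST00000111754.8 from 21.7% ± 2.81 to 2.01% ± 0.270 (SD, n = 4 each). In Sar1a, a GTPase of vesicle export, the main transcript ENSMUST00000020285.9 went from 95.1% ± 1.26 to 66.1% ± 5.15 while the coding transcript ENSMUST00000219506.1 went from 2.04% ± 1.18 to 28.5% ± 3.94 (SD, n = 4 each). In Phb (prohibitin), ENSMUST00000125172.7 went from 90.4% ± 3.05 to 59.5% ± 4.98 (SD, n = 4 each). In Slc25a37, a mitochondrial iron importer, the coding transcript ENSMUST00000037064.4 went from 27.6% ± 3.75 to 69.6% ± 6.00, and a retained-intron transcript from 70.7% ± 3.31 to 30.4% ± 6.00 (SD, n = 4 each).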

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

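The test of immune-cell markers and both tests on Sox2 were chosen only after the result was seen. Over the 119 named genes and both groups, 238 sets of 4 libraries were searched for a library far from the other 3 by Dixon's criterion, which chance meets about 1 time in 20, or 11.9 times here; 18 sets met it. In knockout library 2, Slfn4 (157.4 CPM, next highest 9.73), Ifi204 (61.3 CPM, next 7.91), Ifit1 (217.4 CPM, next 27.7), Wtap (115.8 CPM) and Cbll1 (39.1 CPM) stood above the rest of the group. In knockout library 1, Egfl6 stood high (2.11 CPM) and Cdk1 low (61.1 CPM). In wild-type library 4, Slfn2 (0.115 CPM), Slfn4 (0.0575 CPM), Ifit1 (0.460 CPM) and Sult1d1 (68.5 CPM, next 17.6) stood high. In wild-type library 1 the same held for Lce3a (0.365 CPM), Lce3c (1.02 CPM) and Fbln1 (50.9 CPM). Slfn2, Slfn4 and Lce3a had only 2, 1 and 5 wild-type counts, with 0 in the other wild-type libraries. Any count would be flagged in such a set, so the chance rate given above does not hold for it. In wild-type library 3, Igf2bp2 stood low (7.58 CPM) and Ripk3 (11.7 CPM) and Hmox1 (10.7 CPM) high, and in wild-type library 2 Lfng stood high (36.3 CPM).

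Genes used by myeloid cells (S100a8, S100a9, Slfn4, Chil1 and Plac8, chosen after their values were seen) and interferon-stimulated genes were higher in the knockout, though in knockout library 3 the interferon list was not higher in sum (386 CPM against 434 to 549.7 in wild type), while single members such as Oasl1 were (17.7 CPM against at most 0.365). The 5 genes summed to 5.04 ± 4.41 CPM in wild type and 882.6 ± 782.8 CPM in the knockout (SD, n = 4 each). Immune cells carried through the sort, which excluded them, would bring their general markers. The rise of 25 leukocyte markers, from 17.9 ± 1.35 to 49.1 ± 6.04 CPM in sum, was 3.55% of the rise of the 5 genes (2.83% to 5.86% with 1 knockout library left out), under the bound of 10%, with Arhgdib (11.5 to 33.3 CPM), Cd68 (2.41 to 6.58 CPM) and Cxcr2 (1.04 to 5.21 CPM) making up most of it, and the other 22 markers stayed under 1 CPM in the knockout, among them Ptprc at 0.202 CPM, Tyrobp at 0.0299 CPM and Lyz2 at 0.213 CPM. The presence of males among the wild type alone does not account for it either, since among female libraries the median log2 fold change of the 5 genes and the list kept 100.7% of its size (4.10 against 4.07), though Slfn4 did not pass there (edgeR adjusted p = 0.0712) and 13 of the list rose, against 26 with all 8 libraries. Expression of these genes by the epithelial cells after Mettl3 loss may therefore account for the pattern, as a hypothesis, and the difference among knockout libraries stays open, as do reads shared within gene families and any effect of the Cre or its induction, which were not tested.

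Sox2 was lower in the knockout at close to 1 allele's worth. If the CreER insertion silences 1 Sox2 allele, the ratio would be 0.5. The ratio of 0.494 (95% interval 0.419 to 0.582) does not exclude this, but the pattern was named from that ratio, so it decides nothing more. If fewer basal cells were sorted, basal genes would fall with Sox2, and the basal keratinocyte list had a median log2 fold change of -0.94 (interquartile range 1.07) beside -1.02 for Sox2. Its members went both ways, Krt14 being the 1 that rose, and its summed level went from 23437 ± 2473 to 17539 ± 2597 CPM (SD, n = 4 each). The allele and the loss of basal cells cannot be told apart, since the labels do not say whether the wild-type mice carried CreER and the basal fall had been seen before it was tested. A response of Sox2 to the loss of Mettl3 was not tested and stays open.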

How the results depend on the processing

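The tests with sex as a covariate, on female libraries alone, without X and Y genes and with TMM factors from less abundant genes were chosen only after the result was seen. Changed genes numbered 2332 at 2-fold or more (1236 higher, 1096 lower), by that setting's own construction, and stayed within 1.5 times under every other setting; the range with 1 library left out was 6058 to 6945 (3116 to 3498 higher, 2923 to 3447 lower). Lists past the threshold went from 11 to 0 with an estimated correlation and ranged from 11 to 13 with 1 library left out. With sex as a covariate 2338 transcripts changed; the cause was not tested. Among female libraries alone, with fewer samples, 1581 transcripts changed and 94 genes changed transcript use. With 1 library left out, transcripts ranged from 3507 (without knockout library 3; 3587 without wild-type library 4) to 5245, and transcript use from 175 (without wild-type library 2) to 419, with 229 and 271 without wild-type library 1 or 4 and 216, 237 and 266 without knockout library 2, 3 or 4; the cause was not tested. Of the comparisons of named genes with a setting, 2820 kept their side of the threshold, 141 lost the call and 2 gained it. For lists the numbers were 412, 18 and 12. No named gene or list reversed where it passed in the main test or in the other setting. Direction was not compared where neither passed. There, the lineage transcription factor and immediate-early lists took opposite directions by limma camera and limma fry. With the length offset and with each TPM test 1 other gene was called opposite, not necessarily the same gene. The share of changed genes that were higher lay between 46.3% and 53.1%. Sex as a covariate, as planned for both sexes in both groups, was not run. No paired analysis was possible because the labels give no replicate numbers.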

Other observations

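Apart from the fixed lists, genes were grouped by the stem of their symbol, and the 135 groups with 10 or more tested members were compared by tests chosen only after the result was seen. Subunits of the mitochondrial ribosome were higher, with 20 of 29 Mrps genes past the gene-level test and 0 lower, among them Mrps34 (log2 fold change 1.54, SE 0.10, edgeR adjusted p = 2.83e-05) and Mrps2 (1.52, SE 0.10), and 31 of 50 Mrpl genes higher with 4 lower. Members of the mitochondrial import machinery (Timm, 10 of 14 higher, 0 lower) included Timm8a1 (1.61, SE 0.14) and Timm17a (1.25, SE 0.11). Nucleoporins (Nup) were higher in 15 of 20 cases and lower in 1, with Nup50 at 1.11 (SE 0.11). Regulatory subunits of the proteasome (Psmd) were higher in 11 of 14 and lower in 0, with Psmd7 at 1.17 (SE 0.11); with library totals alone 9 were higher and 1 lower. Members of the 70-kDa heat-shock family (Hspa) were higher in 8 of 10 and lower in 1.

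Histone genes detected in these poly(A)-selected libraries were lower in 12 of 18 cases and higher in 0, with Hist2h2be at -3.20 (SE 0.37, edgeR adjusted p = 0.000178) and Hist1h1c at -1.95 (SE 0.17); near-identical copies can share reads. Intraflagellar transport genes (Ift), which serve the cilium, were lower in 7 of 14 cases and higher in 1, with Ift172 at -1.56 (SE 0.16) and Ift122 at -1.29 (SE 0.12). Directions of these groups held with DESeq2 size factors and with library totals alone. By limma camera 12 groups passed, 8 higher and 4 lower, the rest being Sprr, Mcm, Rpl and Rps, and with an estimated correlation 0 passed (smallest adjusted p = 0.873).

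The gene, transcript and transcript-use counts were highest in the real division among the 35 divisions of the 8 libraries into 4 and 4. That is the strongest result 35 divisions can give, and it makes chance unlikely without excluding it. All other divisions mix knockout and wild-type libraries, so a difference between the groups also lowers their counts of genes, transcripts and transcript use. For lists, divisions that keep most libraries of a group together can pass lists through part of that difference. For genes 1 of the 35 divisions, the real one, gave as many, with 6851 against at most 0 in any other. For transcripts it was again 1, with 5383 against 0. For transcript use it was 1, with 411 against 3. For gene lists chance was not made unlikely, since 17 divisions gave 11 lists or more, and the highest of the others gave 16.

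Long internal exons carry much of the m6A in mRNA, so loss of m6A-dependent decay would raise genes with long ones. Over 11193 protein-coding genes with 3 or more exons, the log2 fold change showed no detectable relation to the longest internal exon when nothing else was held (Spearman rho 0.0107 across genes, which are not independent replicates; permutation p = 0.256, adjusted p = 0.281 over 11 relations). With transcript length, GC content and mean expression held, rho was 0.0502 (bootstrap 95% interval 0.0322 to 0.0693; permutation p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.000157), at the bound of 0.05 set before this value was seen, so the hypothesis that decay shaped the changes may hold only weakly and is not settled. With transcript length alone held rho was 0.0492 (0.0320 to 0.0688), so holding length raised the relation rather than removed it. It was 0.00958 with GC content alone. With length, GC content and mean expression all held the interval stayed positive, which argues against length or GC content carrying that relation. By the bound of 0.05 neither single test decides, because no relation was there to remove before either was held. Both readings were made after the values were seen. Of the other relations, the strongest was with exon junctions per kb of coding sequence (rho -0.111, -0.128 to -0.0915, permutation adjusted p = 0.000157), with nothing else held. The prediction also placed m6A away from exon junctions, so this sign is the one that loss of decay would give. No bound was set for it, and it was not tested with length, GC content or expression held. For 3' UTR length rho was -0.0444 (-0.0629 to -0.0261) and for transcript length -0.0667, with nothing else held. If m6A lies near stop codons, loss of decay would raise genes with long 3' UTRs, and the sign for 3' UTR length is the opposite. For the density of DRACH, the sequence motif of m6A sites, rho was 0.0214 (0.00249 to 0.0417, permutation adjusted p = 0.0327). The signs of these relations thus go both ways and do not settle whether decay shaped the changes. The shares of genes higher and lower did not follow exon length evenly. They were 27.6% and 26.03% for a longest internal exon under 150 nucleotides, 26.9% and 28.7% from 150, 25.8% and 30.2% from 200, 25.8% and 28.5% from 300, 32.9% and 24.9% from 500, and 31.4% and 26.4% from 1000 nucleotides.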
